A study of Mus musculus with 18 samples.

How the data were processed

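RNA sequencing libraries of MC38 cells were grouped by their labels into APC-intact and APC-deleted lines, each without doxycycline and after 24 or 48 h at 1 µM, with 3 libraries in each of 6 groups. The authors deposited whole-number counts per gene for each library; per the submitters' processing notes STAR, HTSeq and mm10 were used, with versions, strandedness and annotation release not given in the sources used here. An RPKM column that the authors deposited beside the counts was not used here. The names of the deposited files carry a designation read here as 2 runs of 9 libraries, which is an inference from that text. On that reading 5 comparisons lay within 1 run or had the run cancel, and 4 set 1 run against the other.

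Entries that name no gene took 22.9 to 25.5% of each library's total, of which reads that were not unique took 16.0 to 17.5%, reads in no annotated gene 4.70 to 7.01% and ambiguous reads 2.02 to 2.21%. They were left out of library sizes and tests. The files hold 39179 genes, of which 25225 had a count and 15006 passed edgeR's filterByExpr by group. Depth ran from 71970499 to 111948430 gene counts per library, and edgeR's common biological coefficient of variation was 8.3%. Replicates differed by more than sampling noise in every pair (chi-square per degree of freedom 7.9 to 81). Each was counted separately, though such a spread may be technical and does not show that they came from separate cultures. Intervals and floors cover counting error and the spread between these libraries only.

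Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, 1 coefficient per group over all 18 libraries, glmQLFit with robust estimation, glmQLFTest), and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. CPM were computed from gene counts and TMM factors. The 9 comparisons, the 26 gene lists, the alternatives and the rule for named genes were chosen before the data were examined. Lists with at least 5 tested genes were tested with camera in limma 3.58.1 on log2 CPM with a preset correlation of 0.01. Camera with the preset correlation called as many lists or more in at least 1 other split of the same samples for 7 of the 9 comparisons. Other splits can keep part of the real difference, so this does not measure chance calls alone. As a caution the text relies on the calls that held with a correlation estimated per list, but these were not put through the splits. Those that held were 1 of 8 lists between the untreated lines, 6 of 11 and 8 of 14 at 24 and 48 h in APC-intact cells, 3 of 11 and 5 of 11 in APC-deleted cells, 2 of 11 and 1 of 9 for the differences, 3 of 10 between the lines at 48 h and 2 of 7 between the times.

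The rule named, among genes with adjusted p under 0.05, at least 5 CPM in the higher group, no overlap of CPM between the groups and an assigned symbol, the 10 largest rises and 10 largest falls of the first 5 comparisons and 5 and 5 of the others, with up to 4 members per list of smallest adjusted p. For the differences between lines the condition on overlap was not applied, since these compare 4 groups. The genes in the text are a part of those the rule admits, picked from them after their values were seen. The alternatives were DESeq2 1.42.0, DESeq-style factors in edgeR, no filter, a replicate block, thinning to the shallowest library (seed 11), only the groups compared, an estimated camera correlation and leaving out each library in turn. Leaving out the 2 libraries with a score beyond 30 on principal component 3 or 4 was added after seeing the data. A prior count of 2 was used for log2 CPM in the component analysis.

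The steps were tested on simulated data for the 24 h comparison in APC-intact cells with 200 changed genes: on 14597 genes edgeR recovered 86% of 100 genes changed 1.5-fold and 98% of 100 changed 2-fold with 10 false calls, and DESeq2 on 15006 genes recovered 95% and 98% with 24. Figures and tables used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Of the identifiers 96.0% were in the GENCODE annotation used to check places, and 99.7% of those lay at the same place. Since the use of strand is not given, 20 of 133 genes checked singly that overlap another tested gene are uncertain, 14 of them with the partner on the opposite strand. Some of the genes checked singly are not reported here, though the counts include them. Those with an overlap in the text are Avil, Angptl7, Aspn, Cxcl10, Gclm, Irf7, Mcm7, Psmb10, Rnf43, Timp1, mt-Nd4 and mt-Nd5. Members of the H2, Magea, Saa, Ifit3 and mitochondrial families can share reads with copies elsewhere.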

Results

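RNA from MC38 cells, a mouse colon adenocarcinoma line, was sequenced in 18 libraries that fell into 6 groups of 3. An APC-intact line and a line with the tumour suppressor gene Apc deleted were each measured without doxycycline and after 24 or 48 h of 1 µM doxycycline, which the labels' protocol used to induce a hairpin against Tdo2. The series addressed what loss of TDO2, the dioxygenase that opens the kynurenine pathway of tryptophan breakdown, does to cells with and without APC. Counts assigned to genes ranged from 71970499 per library (APC-intact at 24 h, replicate 1) to 111948430 (APC-deleted at 24 h, replicate 2), and 15006 genes were tested. Changes are given as log2 fold change ± SE from edgeR with n = 3 per group, and list counts are over all genes tested unless said otherwise. Changes called largest, and genes said to change most, are so only among the genes that the naming rule admits. The labels call the libraries biological triplicates without saying whether they came from separate cultures, so p-values measure the spread between these samples, which may be technical. The labels name the hairpin in the titles of the treated libraries only, whereas their protocol speaks of hairpin cells both treated and untreated, so whether the untreated cells carried it is not settled here. On either reading no treated group lacked the hairpin, so its effect and that of doxycycline cannot be told apart. If the untreated cells lacked it, a difference between them and the hairpin cells from before treatment cannot be told apart either.

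Tdo2 (ENSMUSG00000028011, mm10 chromosome 3 from 81957090 to 81975750, minus strand) was counted in every library at a low level, from 6 to 29 counts. Its mean was 0.228 ± 0.060 CPM (SD, n = 3) without doxycycline, 0.180 ± 0.092 at 24 h and 0.254 ± 0.047 at 48 h in APC-intact cells. In APC-deleted cells the means were 0.166 ± 0.116, 0.108 ± 0.041 and 0.107 ± 0.028 CPM. No treated group passed the test against its untreated group: the fold at 48 h was 1.12 in APC-intact cells (95% interval 0.579 to 2.15, adjusted p = 0.856) and 0.656 in APC-deleted cells (0.311 to 1.39, adjusted p = 0.494). At 24 h the folds were 0.81 (0.41 to 1.6, adjusted p = 0.774) and 0.664 (0.321 to 1.38, adjusted p = 0.573). A fall of Tdo2 by 50% therefore lay within the interval at both times in APC-deleted cells and at 24 h in APC-intact cells. The 48 h interval in APC-intact cells lay above it, but not without untreated replicate 3 or 48 h replicate 3 (lower bounds 0.465 and 0.466). The sign of the estimate turned without 1 library in each comparison: 0.03 without APC-intact 24 h replicate 1, −0.04 at 48 h without untreated APC-intact replicate 3, and 0.09 and 0.06 at 24 and 48 h without untreated APC-deleted replicate 1.

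Apc (ENSMUSG00000005871, chromosome 18 from 34220924 to 34322189, plus strand), which encodes a scaffold that keeps beta-catenin low, was lower in the APC-deleted line by −0.57 ± 0.123 without doxycycline (adjusted p = 0.00241) and by −0.73 ± 0.124 at 48 h (adjusted p = 0.000223). The means were 75.2 ± 3.77 CPM (SD, n = 3) against 111.5 ± 14.1 CPM without doxycycline. Other genes of chromosome 18 were lower too, at a median of −0.138 without doxycycline and −0.164 at 48 h. In the window of 30 neighbouring genes around Apc, 15 were lower and 1 higher without doxycycline, at a median of −0.154. Counts per whole gene cannot show which exons were deleted, so the remaining reads do not check the deletion itself.

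**Figure D1:**
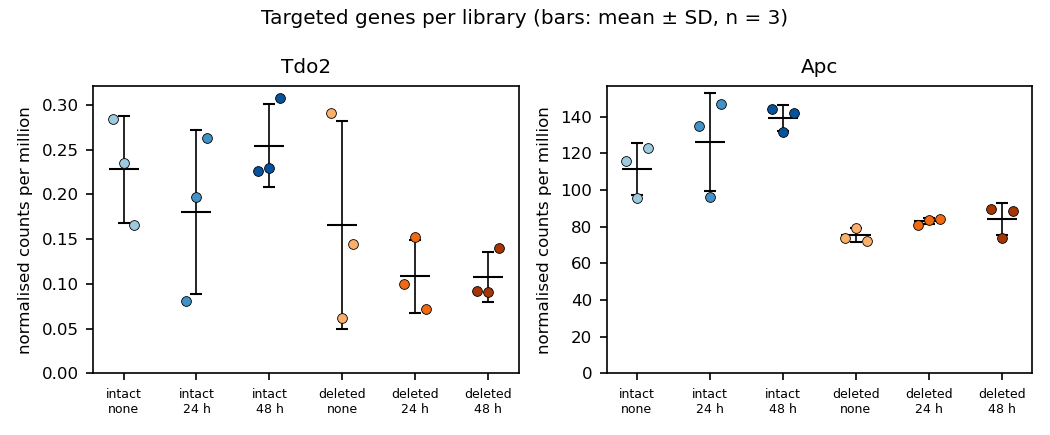
CPM of Tdo2 and Apc in each of the 18 libraries by group, with points for libraries and bars for the mean and SD of 3. Tdo2 lies between 0.0623 and 0.308 CPM, and each treated group overlaps the untreated group of its line. At 48 h all 3 APC-deleted libraries lie below the 3 APC-intact ones for Tdo2, and every APC-deleted library has less Apc than every APC-intact library.

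In a principal component analysis of log2 CPM, the first component held 50.2% of the variance and parted the lines, and the second, on which the untreated libraries of both lines had the highest scores, held 9.4%. APC-intact 24 h replicate 1 stood apart on the fourth component (score 35.1) and APC-deleted 48 h replicate 2 on the third (−34.7).

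**Figure D2:**
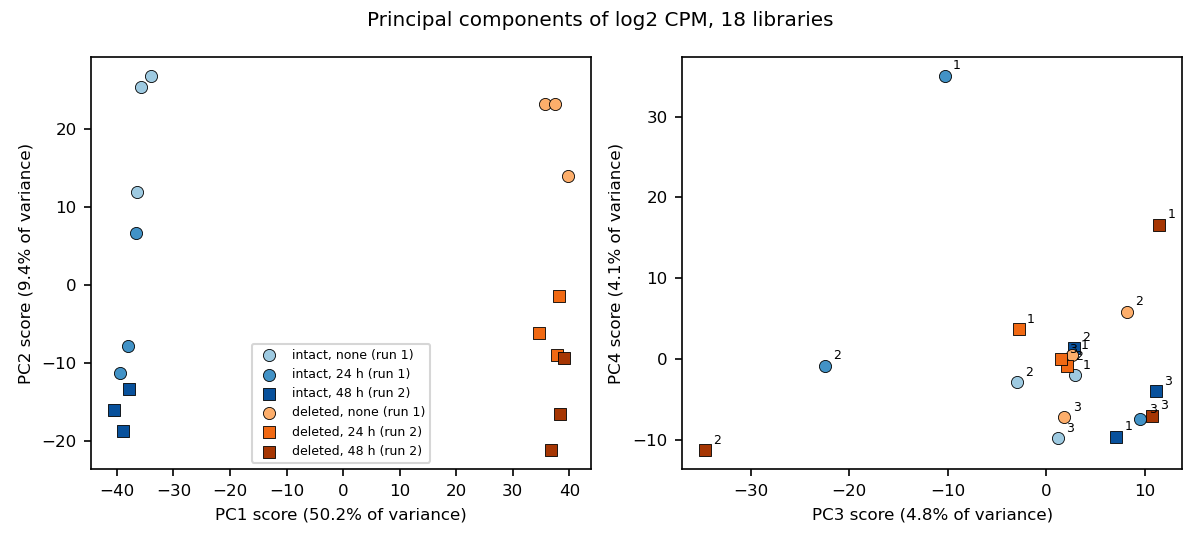
Scores of the 18 libraries on principal components of log2 CPM, with the percent of variance on each axis (50.2% and 9.4% on the first pair, 4.8% and 4.1% on the next), coloured by group. The lines separate on the first component.

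Without doxycycline, where both groups lay in the same run, the lines differed in 4090 genes, 2014 higher and 2076 lower in APC-deleted cells. The share of reads in no annotated gene was 4.82% ± 0.153 (SD, n = 3) in APC-deleted and 5.56% ± 0.489 in APC-intact cells, from 4.70 to 4.99% against 5.25 to 6.12%. The largest rises were in Magea8, a cancer-testis antigen gene (6.01 ± 0.102), Scube3, a secreted glycoprotein (4.14 ± 0.113), and Lrrn4cl (3.79 ± 0.068). Bnc1, a zinc finger transcription factor gene of stratified epithelia, had 0 counts against 1517 and was at least 501-fold lower (floor of 3 counts over the group). Epb4.1l3, a membrane cytoskeleton linker, was at −8.79 ± 0.15 (26 against 11746 counts), Cd28, a costimulatory receptor, at −7.89 ± 0.255 and Mmp2, a gelatinase, at −5.74 ± 0.145. Reads of Magea8 can be shared with related family members, which leaves its size uncertain.

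Among Wnt/beta-catenin targets, 7 of 15 measured genes were higher and 2 lower (9 and 3 adjusted over the list alone). Rnf43 (1.27 ± 0.069) and Axin2 (0.80 ± 0.092), both feedback inhibitors of the pathway, rose, while Apcdd1, another inhibitor (−2.37 ± 0.170), and the receptor gene Ephb2 (−5.72 ± 0.393) fell. The list's median was 0.15 and its mean −0.28. Camera called it up (adjusted p = 0.0314), a call lost with an estimated correlation (adjusted p = 0.25). NRF2 targets, genes of the antioxidant response, were higher in 12 of 19 and lower in 1 (13 and 2 adjusted over the list alone). They included the quinone reductase Nqo1 (1.31 ± 0.051), the glutathione synthesis subunit Gclm (0.64 ± 0.048), Osgin1 (0.80 ± 0.078) and the thioredoxin reductase Txnrd1 (0.45 ± 0.053). This was the list of the 8 called for this comparison that held with an estimated correlation (adjusted p = 0.0269). Aryl hydrocarbon receptor targets were higher in 3 of 6 and lower in 0 (4 and 0 over the list alone), among them Gsta4 and Nqo1, which the NRF2 pathway also drives, and the receptor gene Ahr (0.24 ± 0.070), whose call was lost without untreated APC-intact replicate 2 (adjusted p = 0.0696, 0.000863 to 0.0696 over its alternatives).

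Glycolysis genes fell in 13 of 22 and rose in 3 (14 and 3 adjusted over the list alone). The lactate exporter Slc16a3 (−1.06 ± 0.071), Aldoa (−0.45 ± 0.058) and Pgk1 (−0.43 ± 0.047) fell, and the glucose transporter Slc2a3 rose (1.74 ± 0.086). Hypoxia-inducible factor targets fell in 9 of 18 and rose in 1 (11 and 1 over the list alone), with Bhlhe40, a repressor (−0.51 ± 0.043), and Pdk1, a kinase that restrains pyruvate oxidation (−0.33 ± 0.046), among them. Camera called both lists down, and with an estimated correlation the adjusted p was 0.297 for glycolysis and 0.0911 for hypoxia targets. Of 30 ATF4 and amino acid response genes 10 fell and 0 rose (12 and 0 over the list alone), including Atf3 (−0.58 ± 0.074) and Nars (−0.33 ± 0.049), with adjusted p = 0.399 with an estimated correlation.

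Fibroblast markers were higher in 7 of 15 and lower in 2 (7 and 2 adjusted over the list alone). The collagen gene Col1a1 (0.90 ± 0.058) and Pdgfra (0.60 ± 0.069) rose, and the matrix gene Fbln1 fell (−1.18 ± 0.060). Replication-dependent histones were higher in 5 of 23 and lower in 0 (5 and 0 over the list alone), with Hist1h1c at 0.47 ± 0.082. With an estimated correlation the adjusted p was 0.297 for fibroblast markers and 0.25 for histones; that of aryl hydrocarbon receptor targets was 0.11. Chemokines and myeloid growth factors rose in 10 of 22 and fell in 3 (12 and 4 over the list alone; camera adjusted p = 0.0589), including Csf3, a granulocyte growth factor (1.78 ± 0.157), and Cxcl5 (1.61 ± 0.220).

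The other lists were not called between the untreated lines. Higher and lower counts were 2 and 0 of 12 kynurenine pathway genes (2 and 0 adjusted over the list alone), and 1 and 6 of 33 interferon-stimulated genes (1 and 2). They were 2 and 3 of 17 MHC class I genes (3 and 3) and 6 and 3 of 21 p53 targets (7 and 3). They were 1 and 1 of 26 genes of G2 and M phase (1 and 1) and 3 and 4 of 28 of S phase (3 and 4). Energy genes gave 0 and 1 of 13 mitochondrially encoded mRNAs (0 and 0) and 7 and 0 of 50 nuclear oxidative phosphorylation genes (5 and 0). For 45 mitochondrial ribosome genes they were 2 and 6 (2 and 6), and for 19 cholesterol synthesis genes 0 and 5 (0 and 5). They were for 11 NAD synthesis genes 4 and 2 (5 and 2) and for 66 cytosolic ribosomal proteins 1 and 1 (0 and 0). Epithelial genes gave 2 and 3 of 15 (2 and 3), mesenchymal genes 7 and 4 of 24 (7 and 4) and immediate early genes 3 and 8 of 21 (3 and 9). Haematopoietic markers gave 2 and 3 of 10 (2 and 4) and endothelial markers 3 and 1 of 7 (3 and 1). The median and mean had opposite signs for p53 targets (0.09 and −0.08), NAD synthesis (0.09 and −0.06), mesenchymal genes (0.07 and −0.19), the mitochondrial ribosome, S phase, MHC class I and cytosolic ribosomal proteins.

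**Figure D3:**
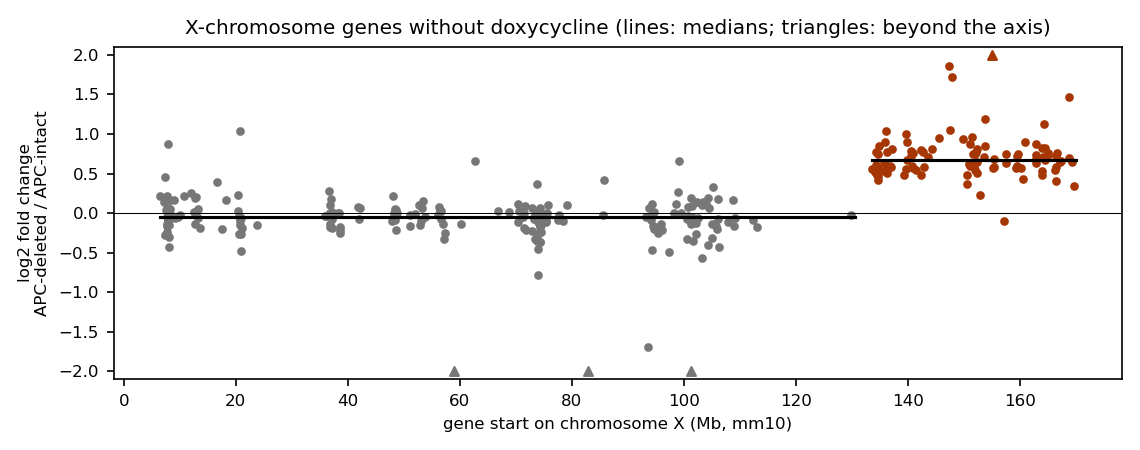
Log2 difference between the untreated lines, APC-deleted minus APC-intact, for genes of at least 5 CPM by mm10 position on chromosome X, with triangles for values beyond the axis. Genes from 133582863 to 170005736 have a median of 0.67 and 97 of 99 were higher, against a median of −0.05 over 224 genes before that segment.

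After 24 h of doxycycline in APC-intact cells, a comparison within 1 run, 846 genes changed, 208 higher and 638 lower. Among genes the naming rule admits, the largest rises included Gpr56, an adhesion receptor (1.52 ± 0.094), and Cdsn, an epidermal adhesion protein (1.40 ± 0.121). They also included Car6, a secreted carbonic anhydrase (0.79 ± 0.071). The largest falls by that rule included Inmt, a methyltransferase of indolethylamines such as tryptamine (−1.59 ± 0.140). Others were Angptl7 (−0.95 ± 0.072), the water channel Aqp1 (−0.83 ± 0.057) and the interferon-induced Ifit3 (−1.17 ± 0.122), whose reads can be shared with Ifit3b. Interferon-stimulated genes fell in 26 of 33 and rose in 0 (30 and 0 adjusted over the list alone; median −0.42), with Cmpk2 at −0.69 ± 0.076, the ubiquitin-like modifier Isg15 at −0.54 ± 0.062 and Usp18 at −0.50 ± 0.067. Chemokines fell in 8 of 22 and rose in 0 (10 and 0 over the list alone), including Ccl9 (−0.79 ± 0.072) and Cxcl10 (−0.42 ± 0.089).

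S phase genes fell in 9 of 28 and rose in 0 (16 and 0 adjusted over the list alone), led by the ribonucleotide reductase subunit Rrm2 (−0.35 ± 0.051). Cholesterol synthesis genes fell in 6 of 19 and rose in 0 (10 and 0 over the list alone), with Fdps, which makes farnesyl diphosphate, at −0.46 ± 0.067. NRF2 targets fell in 9 of 19 and rose in 0 (11 and 0 over the list alone), with Nqo1 at −0.58 ± 0.051. Fibroblast markers fell in 7 of 15 and rose in 0 (9 and 0 over the list alone), among them the collagen genes Col3a1 (−0.54 ± 0.063) and Col6a2 (−0.43 ± 0.062). These 6 lists held with an estimated correlation, at adjusted p from 0.00176 (NRF2 targets) to 0.025 (chemokines and fibroblast markers). The other 5 of the 11 called were lost: MHC class I (0 higher and 6 lower of 17; 1 and 9 over the list alone; adjusted p = 0.159), G2 and M phase (0 and 6 of 26; 0 and 9; 0.189) and hypoxia targets (1 and 2 of 18; 3 and 2; 0.189). So were nuclear oxidative phosphorylation (0 and 3 of 50; 0 and 3; 0.723) and mesenchymal genes (0 and 8 of 24; 3 and 9; 0.103). Hypoxia targets were called up with a median of 0.08 and a mean of −0.09. The share of reads in no annotated gene was 5.56% ± 0.489 (SD, n = 3) without and 6.21% ± 0.541 with doxycycline. The count was 364, 417 and 441 without untreated replicate 1, untreated replicate 2 and 24 h replicate 1, and 258 with only the groups compared in the fit. The large rise of Zfhx2 (0.68 ± 0.172) lost its call without untreated replicate 1 or 2 or 24 h replicate 1 (adjusted p from 0.00214 to 0.14 over its alternatives), and the fall of Idi1 (−0.72 ± 0.159) lost its call without 24 h replicate 1 (0.000366 to 0.069).

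After 48 h in APC-intact cells 1703 genes differed from untreated, 572 higher and 1131 lower. Gpr56 (1.75 ± 0.093) and Cdsn (1.52 ± 0.121) were again among the largest rises. Among the largest falls were Inmt (−1.68 ± 0.140), Nos2, the inducible nitric oxide synthase (−1.51 ± 0.079), the acute phase gene Saa3 (−1.51 ± 0.120), the neutrophil chemokine gene Cxcl1 (−1.44 ± 0.081) and Lcn2, a siderophore-binding protein (−1.17 ± 0.115). Chemokines and growth factors fell in 18 of 22 and rose in 0 (20 and 0 adjusted over the list alone; median −0.87), with the monocyte chemokine genes Ccl7 (−1.29 ± 0.079) and Ccl2 (−1.09 ± 0.068) and the cytokine gene Lif (−0.67 ± 0.051). Interferon-stimulated genes fell in 31 of 33 and rose in 0 (32 and 0 over the list alone; median −0.61), with the transcription factor Irf7 at −1.01 ± 0.073, the nucleic acid sensor Zbp1 at −1.02 ± 0.078 and Isg15 at −0.83 ± 0.062.

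MHC class I genes fell in 10 of 17 and rose in 0 (12 and 0 adjusted over the list alone), including the immunoproteasome subunit Psmb10 (−0.84 ± 0.069) and H2-T23 (−0.70 ± 0.074), whose reads can be shared among H2 genes. S phase genes fell in 11 of 28 (17 over the list alone), cholesterol synthesis in 7 of 19 (7), NRF2 targets in 10 of 19 (15) and fibroblast markers in 9 of 15 (9), with 0 higher in each by both counts. Examples were Rrm2 (−0.32 ± 0.051), Fdps (−0.40 ± 0.067), the haem oxygenase Hmox1 (−0.41 ± 0.055) and Col6a2 (−0.71 ± 0.062). Mesenchymal genes fell in 10 of 24 and rose in 2 (12 and 2 over the list alone). These 8 lists held with an estimated correlation, at adjusted p from 0.000746 (chemokines) to 0.0413 (MHC class I). The other 6 of the 14 called were lost: hypoxia targets (4 higher and 2 lower of 18; 5 and 2 over the list alone; adjusted p = 0.148), ATF4 targets (0 and 4 of 30; 0 and 4; 0.562) and mitochondrially encoded mRNAs (2 and 0 of 13; 2 and 0; 0.562). So were the mitochondrial ribosome (0 and 1 of 45; 0 and 0; 0.571), immediate early genes (0 and 4 of 21; 0 and 7; 0.209) and haematopoietic markers (0 and 2 of 10; 0 and 3; 0.0978). Hypoxia targets were called up with a median of 0.09 and a mean of −0.01. The share of reads in no annotated gene was 6.59% ± 0.38 (SD, n = 3). The treated libraries were in the other run from the untreated ones, so for a single gene run and treatment cannot be told apart by this comparison alone. The count was 822, 901, 853, 1124 and 848 without untreated replicate 1, untreated replicate 2 and 48 h replicates 1, 2 and 3. It was 4367 with only the groups compared, where 46.7% of the calls were higher against 33.6%. The rise of the nuclear RNA Malat1 (1.76 ± 0.457) lost its call without any 1 library but untreated replicate 3 (adjusted p from 0.00107 to 0.115 over its alternatives), and that of mt-Cytb (0.74 ± 0.210) without any 1 of the 6 (0.0072 to 0.155).

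After 24 h in APC-deleted cells 878 genes differed from untreated, 312 higher and 566 lower. Gpr56 (2.15 ± 0.091), Car6 (1.17 ± 0.073) and Angptl4, a lipoprotein lipase inhibitor (0.98 ± 0.102), were among the largest rises. Inmt (−2.09 ± 0.146), the matrix gene Aspn (−1.32 ± 0.154), Ifi27l2a (−1.32 ± 0.143) and Angptl7 (−1.04 ± 0.072) were among the largest falls by the naming rule. Interferon-stimulated genes fell in 19 of 33 and rose in 0 (28 and 0 adjusted over the list alone), including Cmpk2 (−0.56 ± 0.076), Isg15 (−0.43 ± 0.061) and Usp18 (−0.46 ± 0.067), a call lost with an estimated correlation (adjusted p = 0.0693). Chemokines rose in 3 of 22 and fell in 3 (4 and 4 over the list alone), with the growth factor gene Csf2 at 1.03 ± 0.176 and Ccl9 at −0.46 ± 0.071.

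S phase genes fell in 9 of 28 and rose in 0 (10 and 0 adjusted over the list alone), with the helicase subunits Mcm6 (−0.21 ± 0.042) and Mcm7 (−0.22 ± 0.044). Cholesterol synthesis genes fell in 3 of 19 and rose in 0 (6 and 0 over the list alone), with Fdps at −0.43 ± 0.067. Fibroblast markers fell in 8 of 15 and rose in 0 (9 and 0 over the list alone), with Col3a1 at −0.64 ± 0.063 and Col6a1 at −0.54 ± 0.069. These 3 lists held with an estimated correlation, at adjusted p = 0.0137, 0.0193 and 0.0137. Mitochondrially encoded mRNAs rose in 6 of 13 and fell in 0 (8 and 0 over the list alone; median 0.97), with mt-Cytb, a subunit of respiratory complex III, at 1.53 ± 0.214, and the call was lost with an estimated correlation (adjusted p = 0.15). The mitochondrial share of gene counts was 0.373% ± 0.107 (SD, n = 3) against 0.203% ± 0.065 without doxycycline, and that of reads in no annotated gene 5.43% ± 0.142 against 4.82% ± 0.153. Also called and lost were MHC class I (0 higher and 4 lower of 17; 0 and 6 over the list alone; adjusted p = 0.235), p53 targets (3 and 0 of 21; 6 and 1; 0.15) and glycolysis (0 and 2 of 22; 0 and 4; 0.249). So were nuclear oxidative phosphorylation (0 and 2 of 50; 0 and 2; 0.452), NRF2 targets (0 and 2 of 19; 0 and 5; 0.075) and mesenchymal genes (0 and 8 of 24; 2 and 10; 0.075). The groups lay in different runs. The count was 494, 533 and 518 without untreated replicates 1, 2 and 3, and 521, 428 and 463 without 24 h replicates 1, 2 and 3. It was 1374 by DESeq2 and 2473 with only the groups compared, where 48.6% of the calls were higher against 35.5%. The rise of mt-Nd4 (1.11 ± 0.247) lost its call without untreated replicate 1 or 2 or 24 h replicate 1 or 2 (adjusted p from 0.000358 to 0.116 over its alternatives), and that of mt-Nd5 (0.97 ± 0.202) without 24 h replicate 1 or 2 (8.59e-05 to 0.124).

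After 48 h in APC-deleted cells 1653 genes differed from untreated, 679 higher and 974 lower. Gpr56 rose by 2.42 ± 0.092, mt-Cytb by 1.60 ± 0.214 and Avil, an actin-binding protein, by 1.18 ± 0.101. Aspn (−1.55 ± 0.157), Inmt (−1.49 ± 0.142), the platelet chemokine gene Ppbp (−1.38 ± 0.138), Csf3 (−1.24 ± 0.154) and Nos2 (−1.02 ± 0.078) were among the largest falls. Chemokines fell in 11 of 22 and rose in 0 (12 and 0 adjusted over the list alone), including Ccl7 (−0.84 ± 0.078), Ccl2 (−0.76 ± 0.067) and Cxcl1 (−0.75 ± 0.080). Interferon-stimulated genes fell in 21 of 33 and rose in 0 (25 and 0 over the list alone), with Zbp1 at −0.70 ± 0.078 and Isg15 at −0.58 ± 0.062, and the call was lost with an estimated correlation (adjusted p = 0.0529).

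S phase genes fell in 12 of 28 (15 adjusted over the list alone), cholesterol synthesis in 6 of 19 (7), NRF2 targets in 7 of 19 (8) and fibroblast markers in 7 of 15 (8), with 0 higher in each by both counts. Examples were Rrm2 (−0.31 ± 0.051), Fdps (−0.54 ± 0.067), Hmox1 (−0.43 ± 0.055), Srxn1 (−0.30 ± 0.047) and Col3a1 (−0.75 ± 0.063). With chemokines these 5 lists held with an estimated correlation, at adjusted p from 0.00789 (S phase) to 0.0214 (cholesterol synthesis). Mitochondrially encoded mRNAs rose in 7 of 13 and fell in 0 (11 and 0 over the list alone; median 1.03; adjusted p = 0.113 with an estimated correlation), beside a mitochondrial share of 0.383% ± 0.085 (SD, n = 3) of gene counts. Reads in no annotated gene held 5.67% ± 0.425 (SD, n = 3). Also called and lost were MHC class I (0 higher and 5 lower of 17; 0 and 5 over the list alone; adjusted p = 0.289), glycolysis (0 and 6 of 22; 0 and 7; 0.289), mesenchymal genes (2 and 9 of 24; 3 and 12; 0.0529) and cytosolic ribosomal proteins (1 and 0 of 66; 0 and 0; 0.627). The groups lay in different runs. The count was 882, 1032 and 2816 without untreated replicates 1 and 2 and 48 h replicate 2, which stood apart on the third component, and 433 with only the groups compared. The rise of Erdr1 (1.13 ± 0.302), whose reads can come from near-identical copies, lost its call without any 1 of the untreated libraries (adjusted p from 0.00386 to 0.208 over its alternatives), and that of mt-Nd2 (1.09 ± 0.262) without untreated replicate 1 or 2 or 48 h replicate 2 (0.000373 to 0.0801).

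**Figure D4:**
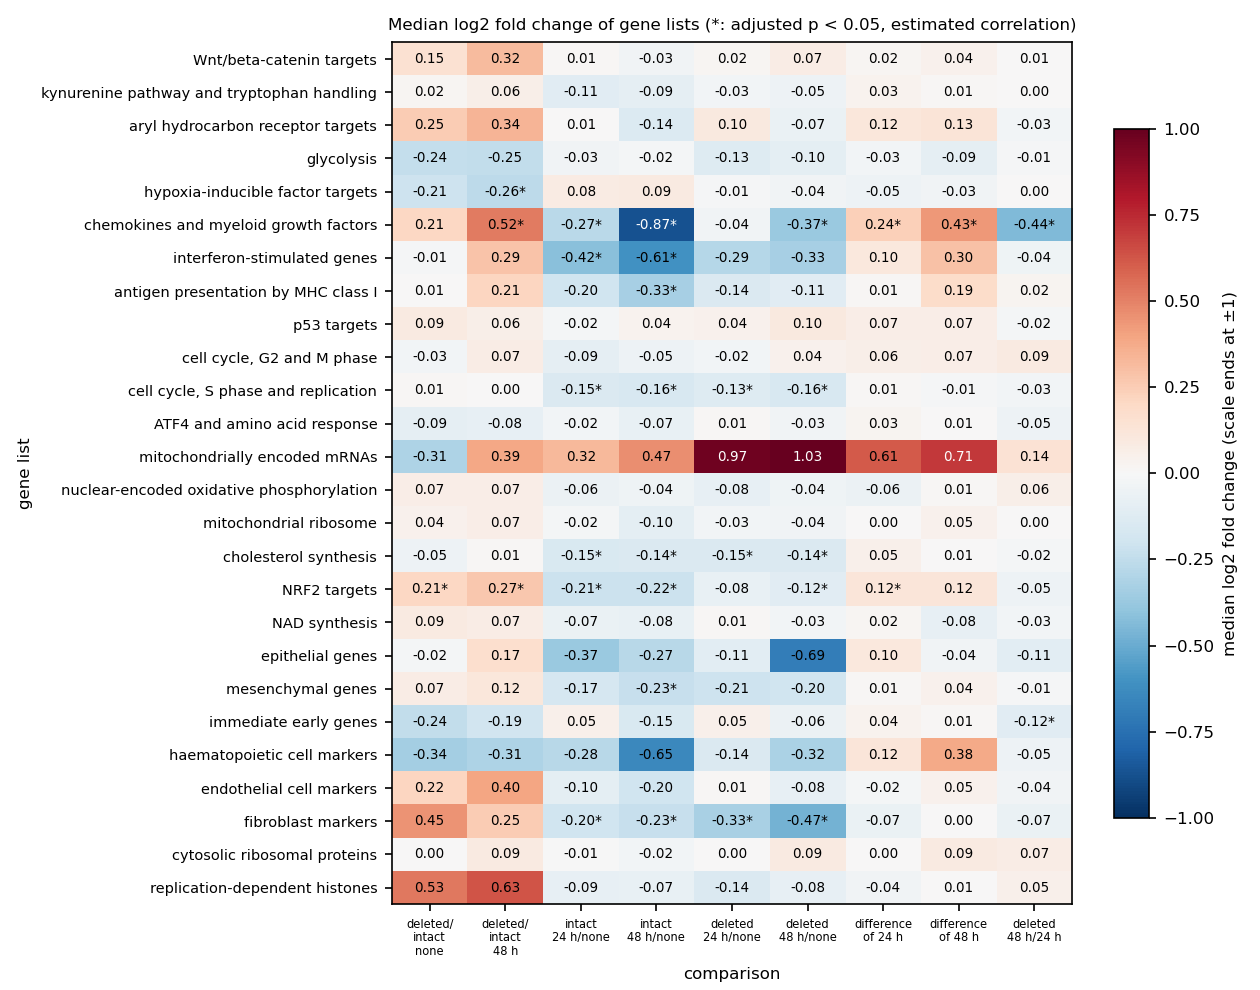
Median log2 change of each of the 26 lists (lines) in each of the 9 comparisons (columns), with an asterisk where the list was called by camera with an estimated correlation. S phase, cholesterol synthesis and fibroblast lists carry an asterisk and a median below 0 in all 4 comparisons of doxycycline with none.

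At 48 h 781 genes were called in both lines in the same direction, 229 higher and 552 lower, where independent lists of those sizes would share 25.9 and 73.4, and 1 was called in opposite directions. Independence here takes every gene as equally likely to be called. Both comparisons also set the same runs against each other, so an overlap can come from the run. Gpr56, Inmt, Nos2 and Cxcl1 were among the shared genes. Of the 878 genes called at 24 h in APC-deleted cells, 97.4% had the same sign in APC-intact cells at 24 h, a comparison within 1 run, as had 91.5% of the 1653 called at 48 h. The overlap was 497, 497, 1651, 477 and 519 without untreated APC-intact replicates 1 and 2, APC-deleted 48 h replicate 2 and APC-intact 48 h replicates 1 and 3, and 367 with only the groups compared.

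The response to doxycycline was compared directly between the lines. At 24 h 1 gene differed: Timp1, an inhibitor of matrix metalloproteinases, by −0.62 ± 0.080 (adjusted p = 0.0037). Its CPM lay between 77.2 and 83.7 in treated APC-intact against 35.9 to 38.6 in treated APC-deleted libraries, and between 54.2 and 57.1 against 38.5 to 41.3 in the untreated ones. At 48 h, where the run cancels from the difference, Timp1 (−0.49 ± 0.080), Mx2, an interferon-induced GTPase (0.83 ± 0.127), Cxcl1 (0.68 ± 0.113) and Bcl2l15 (0.59 ± 0.101) differed. Positive values mean that the change from untreated was more upward or less downward in APC-deleted than in APC-intact cells. They do not give the gap in level between the treated lines. Chemokines as a list differed at 24 h (7 higher and 0 lower of 22 adjusted over the list alone, 0 over all genes; median 0.24; adjusted p = 0.0113 with an estimated correlation) and at 48 h (10 and 0 over the list alone, 1 and 0 over all genes; median 0.43; 0.00309). NRF2 targets differed at 24 h (median 0.12; adjusted p = 0.0113 with an estimated correlation) with 0 of 19 genes passing by either count. Interferon-stimulated genes at 48 h (25 and 0 of 33 over the list alone, 1 and 0 over all genes; median 0.30) lost their call with an estimated correlation (adjusted p = 0.0517).

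With no difference at all, a share of 0.05 of the 15006 genes tested would have an unadjusted p under 0.05. By the edgeR test 613 genes had such a p at 24 h, fewer than that share, and 1051 at 48 h, more than it. By adjusted p DESeq2 called 4 and 56. The count at 24 h was 2 without untreated APC-intact replicate 3, untreated APC-deleted replicate 3 or APC-intact 24 h replicate 3. At 48 h it was 0 without untreated replicate 1 or 2 of either line, APC-deleted 48 h replicate 1 or 3 or APC-intact 48 h replicate 2 or 3. It was 2 without untreated APC-deleted replicate 3 or APC-intact 48 h replicate 1, and 0 with only the groups compared. The adjusted p of Bcl2l15, Cxcl1, Mx2 and Timp1 at 48 h ranged up to 0.352, 0.265, 0.25 and 0.265 over their alternatives. The 24 h difference set APC-deleted libraries of both runs against APC-intact libraries of 1 run, so its APC-deleted part cannot be told apart from the run.

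**Figure D5:**
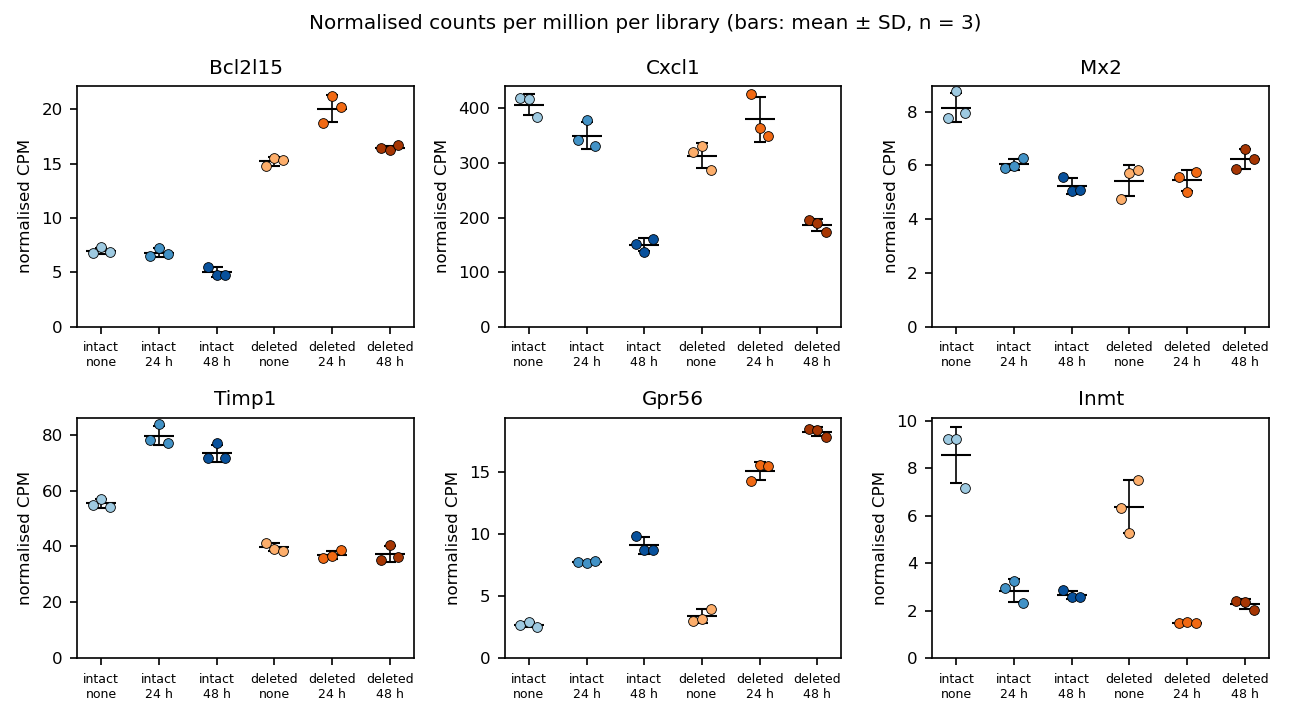
CPM of the 4 genes called for a difference between the lines (Timp1, Mx2, Cxcl1, Bcl2l15) and of the largest rise and fall at 24 h in APC-intact cells (Gpr56, Inmt) in each library by group, with points for libraries and bars for the mean and SD of 3. Gpr56 lies between 2.52 and 4.01 CPM in untreated libraries and between 7.70 and 18.5 in treated ones.

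At 48 h of doxycycline, within 1 run, the lines differed in 5203 genes, 2678 higher and 2525 lower in APC-deleted cells. The share of reads in no annotated gene again did not overlap, at 5.25 to 6.10% in APC-deleted and 6.27 to 7.01% in APC-intact libraries. Magea8 (6.01 ± 0.103), Scube3 (3.86 ± 0.110) and Gsta4, a glutathione transferase (3.07 ± 0.10), were among the largest rises. Ptprk, a receptor tyrosine phosphatase gene, had 0 counts against 1575 (at least 485-fold lower, floor of 3 counts over the group), and Epb4.1l3 fell by 9.76 ± 0.166. Chemokines were higher in 15 of 22 and lower in 1 (16 and 1 adjusted over the list alone; median 0.52; adjusted p = 0.0356 with an estimated correlation), with Csf3 at 2.35 ± 0.182. NRF2 targets were higher in 13 of 19 and lower in 2 by both counts (0.0127), with Nqo1 at 1.44 ± 0.052, and hypoxia targets lower in 12 of 18 and higher in 0 by both counts (0.023), with Bhlhe40 at −0.42 ± 0.043. Interferon-stimulated genes were higher in 22 of 33 and lower in 0 (23 and 1 over the list alone), with Irf7 at 0.49 ± 0.073, a call lost with an estimated correlation (adjusted p = 0.382). Wnt/beta-catenin targets were higher in 8 of 15 and lower in 2 (8 and 3 over the list alone; median 0.32, mean −0.23), with Rnf43 at 1.31 ± 0.069, and their call up was lost too (adjusted p = 0.294 with an estimated correlation). Tdo2 was at −1.23 ± 0.497 (adjusted p = 0.0628), and 0.0326 with only the groups compared, over alternatives from 0.0326 to 0.177. Across 15006 genes, which are not independent replicates, the line difference at 48 h and without doxycycline had Pearson r = 0.847 and Spearman rho = 0.689. Of them, 3285 genes were called in both comparisons in the same direction and 6 in opposite directions.

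Between 24 and 48 h in APC-deleted cells, within 1 run, 78 genes changed, 11 higher and 67 lower. Csf3 (−1.87 ± 0.154), Lcn2 (−1.40 ± 0.116), Nos2 (−1.10 ± 0.078) and Cxcl1 (−1.03 ± 0.080) fell most, and Klhl30 (0.58 ± 0.073) and the matrix gene Tgfbi (0.48 ± 0.055) rose. Chemokines fell in 11 of 22 and rose in 0 (13 and 2 adjusted over the list alone; median −0.44; adjusted p = 0.00137 with an estimated correlation), with Ccl2 at −0.65 ± 0.067 and Ccl7 at −0.66 ± 0.078. Immediate early genes fell in 1 of 21 and rose in 0 (5 and 0 over the list alone; 0.0352), the 1 being Ier3 (−0.49 ± 0.063). The count was 47 and 193 without 24 h replicate 2 and 48 h replicate 2, 22 with only the groups compared, and 188 by DESeq2, where 31.4% of the calls were higher against 14.1%. The number of lists called was 7, and 4 without 48 h replicate 2.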

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

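The splits of the samples reported here were set out before their results were seen. The check of which splits kept the treatment groups of 1 line was chosen afterwards. Each result below stood out because the response to doxycycline differed between the lines by a test of the difference itself, APC-deleted minus APC-intact. At 24 h this held for Timp1 (log2 difference −0.62), a difference whose APC-deleted part cannot be told apart from the run. In APC-intact cells, within 1 run, Timp1 lay between 54.2 and 57.1 CPM untreated and between 77.2 and 83.7 CPM at 24 h. At 48 h, where the run cancels, it held for Timp1 (−0.49), Mx2 (0.83), Cxcl1 (0.68) and Bcl2l15 (0.59).

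With the preset correlation, camera called 11 lists for the difference at 24 h. The adjusted p was 1.47e-10 for chemokines and myeloid growth factors, 4.78e-07 for mitochondrially encoded mRNAs, 4.56e-06 for NRF2 targets, 1.24e-05 for interferon-stimulated genes, 0.00742 for G2 and M phase genes, 0.0166 for hypoxia targets, 0.0181 each for aryl hydrocarbon receptor targets, glycolysis and p53 targets, 0.025 for nuclear oxidative phosphorylation and 0.0354 for fibroblast markers. Chemokines and NRF2 targets held with an estimated correlation (adjusted p = 0.0113 each), and the other 9 did not, at adjusted p from 0.252 to 0.44 for all but glycolysis (0.494) and nuclear oxidative phosphorylation (0.805). Hypoxia targets were called down with a median of −0.05 and a mean of 0.04. The count of lists was 7 without untreated APC-deleted replicate 1.

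At 48 h camera called 9 lists, at adjusted p = 5.71e-27 for interferon-stimulated genes, 3.44e-17 for chemokines, 5.69e-07 for MHC class I, 3.34e-06 for mitochondrially encoded mRNAs, 0.000177 for cytosolic ribosomal proteins, 0.000781 for G2 and M phase, 0.00539 for NRF2 targets, 0.00614 for hypoxia targets and 0.0328 for glycolysis. Chemokines held with an estimated correlation (adjusted p = 0.00309). The others did not, at adjusted p from 0.0517 (interferon-stimulated genes) to 0.796 (cytosolic ribosomal proteins).

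At 24 h chance could not be excluded for the number of genes: 14 of 40 splits of the 12 libraries gave as many as the real one, which gave 1, and the highest other gave 8. Of the 37 others that kept the treated and untreated groups of neither line, 11 gave as many and the highest gave 2. Such a count does not say which gene was called, so it does not test Timp1 by itself. At 48 h 6 of 40 gave as many as the real 4, and the highest other gave 3891. That split kept the groups of the APC-intact line and exchanged all treated and untreated libraries of the APC-deleted line. Its contrast therefore added the responses of both lines. The 5 others with as many, that split among them, all kept the treated and untreated groups of the APC-intact line. Their difference therefore held that line's own response and does not measure chance. In all 12 other splits kept the groups of a line, and those besides these 5 gave fewer than the real 4. The 27 splits that kept the groups of neither line gave at most 1 gene, but they mix treated with untreated libraries, which can widen the spread. These splits therefore do not decide about chance for the genes at 48 h. For lists, 6 of 40 splits gave as many as the real 11 at 24 h (highest other 12) and 21 of 40 as many as the real 9 at 48 h (highest other 15). Among the others that kept the groups of neither line these were 3 of 37 (highest 12) and 11 of 27 (highest 14). Splits that exchange libraries in opposite senses in the lines leave part of the response shared by both in the difference. Their counts therefore do not measure chance alone, and the splits do not decide about chance for lists at either time.

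Comparisons of 3 libraries with 3 have 10 splits, too few for a share under 0.05. The real split alone gave as many genes (1 of 10) in each of the 7 such comparisons. Every other split mixed libraries of both groups, which can widen the spread, so its low count of genes does not show what chance gives. The real and highest other counts were 4090 and 0 between the untreated lines, 846 and 0 at 24 h and 1703 and 1 at 48 h in APC-intact cells, 878 and 1 at 24 h and 1653 and 1 at 48 h in APC-deleted cells, 5203 and 0 between the lines at 48 h and 78 and 1 between the times. For lists, the same 7 comparisons gave 8 and 8, 11 and 11, 14 and 15, 11 and 9, 11 and 10, 10 and 11, and 7 and 8, with 1 of 10 splits giving as many at 24 and 48 h in APC-deleted cells and 2 of 10 in the other 5. The other splits mix the groups unevenly and keep part of the real difference, so their list counts do not measure chance alone. For the overlap of genes changed at 48 h in both lines, 1 of 40 splits gave as many as the real 781 and the highest other gave 1. This does not show that the lists of the 2 lines share more than chance gives, since other splits of 1 line's 6 libraries at 48 h called at most 1 gene, which leaves nothing to share.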

How the results depend on the processing

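Leaving out APC-intact 24 h replicate 1 and APC-deleted 48 h replicate 2 together was chosen after seeing the data, and the other alternatives were not. Of 232 results of genes checked singly, Tdo2 against untreated groups aside, 0 turned direction, and the call was lost in 0 with DESeq2 or RLE factors, 8 with no filter, 4 with the replicate block, 4 with thinning and 26 with only the groups compared, where 1 was gained. It was lost in 30 without at least 1 library and in 6 of 109 without the 2 libraries. Where no construction of the alternative is named, the cause was not tested.

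With only the groups compared, which estimates the spread from fewer samples, changed genes numbered 258 and 4367 at 24 and 48 h in APC-intact cells, 2473 and 433 in APC-deleted cells, 0 for the 48 h difference and 22 between the times. The overlap was 367 and the correlation of the line effects 0.898. DESeq2 gave 1374 genes at 24 h in APC-deleted cells, 4 and 56 for the differences and 188 between the times. Without a filter the 48 h difference had 14 genes and the 24 h difference 6 lists. Without the 2 libraries, counts were 3009 at 48 h in APC-deleted cells, 2 for the 48 h difference and 221 between the times, with 4 lists for the last, an overlap of 1756, a correlation of 0.84 and Tdo2 at 0.023 at 24 h in APC-intact cells, where it turned sign. Thinning gave a correlation of 0.855. With an estimated camera correlation, lists called were 1 between the untreated lines, 6 and 8 at 24 and 48 h in APC-intact cells, 3 and 5 in APC-deleted cells, 2 and 1 for the differences, 3 between the lines at 48 h and 2 between the times.

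Leaving out 1 library, counts ranged from 364 to 1259 and from 822 to 1409 at 24 and 48 h in APC-intact cells, from 428 to 533 and from 882 to 2816 in APC-deleted cells, from 1 to 2 and from 0 to 3 for the differences and from 47 to 193 between the times. Between the lines they were 3101 to 3579 untreated and 4231 to 5219 at 48 h. Lists ranged from 7 to 13 for the 24 h difference and from 4 to 9 between the times. The overlap ranged from 477 to 1651 and the correlation from 0.82 to 0.84. Tdo2 ranged from −0.671 to 0.031 and from −0.036 to 0.346 at 24 and 48 h in APC-intact cells and from −0.993 to 0.088 and from −1.012 to 0.062 in APC-deleted cells, so its sign rested on single libraries of 6 to 29 counts. DESeq2 gave no adjusted p for Tdo2 at 48 h in APC-intact and 24 h in APC-deleted cells.

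The replicate numbers did not pair the samples: in 1 of 15 pairs of groups were all same-number correlations over 0.1, their range was −0.178 to 0.531, and in 18 of 45 comparisons of a library with another group it correlated best with its own number. With the replicate block the counts were 4261 between the untreated lines, 965 and 2173 in APC-intact cells, 988 and 1801 in APC-deleted cells, 1 and 3 for the differences, 5373 between the lines at 48 h and 86 between the times, with an overlap of 956 and a correlation of 0.848. Tdo2 was then −0.306, 0.155, −0.561 and −0.598 at 24 and 48 h in APC-intact and APC-deleted cells.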

Other observations

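The tests of the runs at both times, of ATF4 targets, of the depth behind Tdo2 and of the remainder of chromosome X were chosen only after the results were seen, and those of cells without the hairpin, of an extra copy and of random gene orders before.

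Genes near the end of chromosome X were higher together in the APC-deleted line. Between 133582863 and 170005736 (mm10, from Pcdh19 to Mid1), 97 of 99 genes of at least 5 CPM were higher and 0 lower without doxycycline, at a median log2 difference of 0.67 (quartiles 0.57 to 0.79, fold 1.59), and 94 were higher at 48 h. The segment's median lay between 0.54 and 0.77 in the 9 APC-deleted libraries and between −0.12 and 0.05 in the 9 APC-intact ones. Magea8, the largest rise between the lines, lies in it. Whole chromosomes shifted less, with chromosome 12 at a median of 0.15 and chromosomes 18 and 5 at −0.14 and −0.12 (permutation p = 0.0001 each, the smallest that 10000 random orders can give, and adjusted p = 0.00025). Chromosomes 2, 11, 13, 14 and 15 had the same permutation p, at medians from −0.035 to 0.088. The p therefore does not set chromosomes 12, 18 and 5 apart, and random orders treat genes as independent.

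A run of neighbours by chance was argued against by a permutation test: the largest median over 327 windows of 30 genes was 0.71, against at most 0.26 in 100000 random orders (p = 1e-05, the smallest they can give). A change of the whole chromosome was argued against by the 224 genes before the segment, at a median of −0.051. An extra copy of the segment in the APC-deleted line, which predicts 1 common factor at any level, is a candidate explanation: the medians of its 33 genes of lowest and 33 of highest CPM differed by 0.073, under the bound of 0.15 set beforehand. RNA counts do not measure copy number, and a ratio of the lines does not say which of them changed, so this stays a hypothesis. A difference that arose when the line was derived or cultured was not separated from the deletion of Apc.

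At 48 h 781 genes were called in both lines in the same direction. A difference between the runs as its whole cause was argued against, since 91.5% of the 1653 genes called at 48 h in APC-deleted cells, across runs, had the same sign in APC-intact cells at 24 h, within 1 run. Of the genes called at 24 h in APC-deleted cells 97.4% did. A block of mitochondrial translation by doxycycline seen through ATF4 targets stays open. That list's median was −0.024 at 24 h in APC-intact cells, so the rise of ATF4 targets that such a block predicts was not seen there. Mitochondrially encoded mRNAs, however, had medians above 0 (0.32 and 0.47 at 24 and 48 h in APC-intact cells, 0.97 and 1.03 in APC-deleted cells) without passing with an estimated correlation. Doxycycline acting without the hairpin could not be tested, because 0 groups of hairpin-free cells received it. The effect of doxycycline and that of the hairpin cannot be told apart, and either may have given the response. If the untreated cells lacked the hairpin, a difference between them and the hairpin cells from before treatment may also have given it.

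Tdo2 was not called lower in any comparison of doxycycline with none. Too few counts to see a fall by 50% stays open in both lines. The lower bound of the fold was 0.41 at 24 h in APC-intact cells and 0.321 and 0.311 at 24 and 48 h in APC-deleted cells, and these intervals also held 1. At 48 h in APC-intact cells the bound was 0.579, but it was 0.465 without untreated replicate 3 and 0.466 without 48 h replicate 3. Levels of TDO2 protein were not analysed here.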
